A study of Drosophila melanogaster with 4 samples.

How the data were processed

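DREF was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) with a rabbit polyclonal antibody in Kc167 cells, an embryonic cell line of Drosophila melanogaster. Per the labels, 4 libraries were made, 2 from a sample called total and 2 from a sample called mitosis. The labels' protocols describe formaldehyde crosslinking, sonication, immunoprecipitation on protein A beads, adaptor ligation, PCR and gel selection of short fragments. How mitotic cells were obtained is not given in the sources used here. The submitters state that the libraries were not paired for analysis, and that input controls came from earlier series, which were not used here.

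Reads were aligned with Bowtie 0.12.5, per the submitters' processing notes. The peak caller, its threshold, the handling of duplicate reads and the genome build are not given in the sources used here. The names of the sequences in the lists, such as Uextra and XHet, are those of genome Release 5 (dm3), and coordinates are given as deposited, with starts counted from 1. The authors deposited 1 peak list for each condition and no list for a single library. Whether the reads of both libraries were pooled is not stated, nor whether the total list was called on reads apart from those of the mitotic libraries. Each row of a deposited list holds a sequence name, a start, an end and an unlabelled score per peak with at most 2 decimals. This deposited score has no stated unit. It was used to order peaks and compare medians within a list, and to describe how scores of overlapping peaks were related between the lists. The steps of its values were also compared between the lists, under an assumption stated in the closing section. An alternative given in the Results and in the section on processing rests on the same assumption. The lists hold no read counts, so the depth of each library is unknown. There are no replicate values: each list counts as 1 value per condition, and no test between the conditions across libraries was possible.

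What was computed from the lists is as follows. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Total peaks were then split into shared and total-only, and the mitotic peaks without a total peak were called mitotic-only. The overlap was compared with 1000 circular shifts of the mitotic peaks within each sequence, one-sided, with the last peak end of either list taken as the sequence end. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent. Where a count was 0, the upper limit was set at 3 counts of the total. Differences of median score used two-sided permutation tests with 100000 resamples over peaks, which are not biological replicates. Chromosomes were compared by Fisher's exact test, two-sided, and peak density by a two-sided permutation test over 1-Mb bins. The 20 density tests were adjusted together by the Benjamini-Hochberg method, and neighbouring bins are not independent. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

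The tests were tested on simulated data. Among 20 simulated pairs of independent lists for the comparison of mitotic and total peaks on the main arms (929 mitotic peaks), 0 passed 0.05. Of the pairs with a planted overlap, 20 of 20 passed. Apart from the planted overlap, peaks were placed uniformly along each arm, and fewer shifts were used than for the data. Regional clustering and reads common to both lists were not simulated. For the comparison of scores, 3 of 50 simulated sets of 400 peaks without a difference and 50 of 50 with a difference of 1 SD passed. These sets had normally distributed scores and groups of equal size, so they do not give the power for the 21 mitotic-only peaks.

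Peaks to be named were fixed before the data were examined: the strongest peaks of each class near genes if an annotation of the build was at hand, otherwise the 3 strongest peaks of each class by coordinates. The gene table at hand was of Release 6 and no genome sequence was at hand, so the second rule applied. Planned comparisons of promoters, of the DREF sequence motif and of gene lists were not run for the same reason, and no peak was given a gene, an exon or an intron. Alternatives fixed before the data were examined covered the definition of overlap, the length and strictness of the lists and the sequences included. Shifts of 10 to 100 kb and all tests of density and of peak borders were chosen after seeing the data.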

Results

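The distribution of DREF, a zinc finger protein that binds the DNA replication-related element and is counted by the submitters among the insulator proteins, was compared between total and mitotic Kc167 cells. Kc167 is a line of embryonic origin that grows in serum-free medium. The 2 libraries of each condition are represented by 1 deposited peak list per condition, without replicate values and without read counts. The total list held 1937 peaks that covered 2.08 Mb, and the mitotic list held 1113 peaks that covered 1.03 Mb. Median peak width was 1010 bp in the total list (interquartile range 946 to 1108 bp) and 913 bp in the mitotic list (801 to 1002 bp). The score that the authors gave each peak ranged from 1.8 to 24.69 in the total list, with a median of 5.63. In the mitotic list it ranged from 3.5 to 46.46, with a median of 10.28. The scores of the lists are not on a stated common scale.

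The first question was which DREF sites of total cells were also found in mitotic cells. Nearly all mitotic peaks overlapped a total peak, whereas many total peaks had no mitotic peak. Of the 1113 mitotic peaks, 1092 overlapped a total peak (98.1%, 95% interval 97.1 to 98.8%). Of the 1937 total peaks, 1087 overlapped a mitotic peak (56.1%, 53.9 to 58.3%), and 850 did not. Shifted mitotic peaks overlapped a total peak in a median of 2.61% of cases and at most 4.67%, and both shares exceeded all 1000 shifts (one-sided permutation by circular shifts, p = 0.001, the smallest that these shifts can give). With local shifts of 10 to 100 kb, chosen after seeing the data, the median was 4.85% and the highest share 6.74%. The shifts describe lists placed independently, and it is not stated that the lists were called on separate reads; 154 of the 1092 overlapping pairs had starts identical to the base pair. There were 5 total peaks that spanned 2 mitotic peaks each.

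The strongest shared site lay on 2R at 16771527 to 16772673, with a score of 24.69 in the total list and 41.53 in the mitotic list. The next was on 3L at 505377 to 506734, with scores of 22.34 and 40.71. The third lay in Uextra, the collection of unplaced sequence, at 28635874 to 28637193, with scores of 21.69 and 25.62. The strongest peak of the mitotic list was also in Uextra, at 8791490 to 8793109, with a score of 46.46. Over the 1092 overlapping pairs the scores of the lists rose together across sites, with a Pearson r of 0.92 and a Spearman rho of 0.89. These coefficients are across peaks, which are not independent replicates, and any reads common to both lists would raise them. On the main arms (2L, 2R, 3L, 3R and X) rho was 0.91 over 917 pairs, and in Uextra it was 0.82 over 160 pairs. The mitotic score was above the total score in 1069 of 1092 pairs. The median ratio of mitotic to total score was 1.48 over all pairs, 1.497 on the main arms and 1.28 in Uextra, with no stated common scale.

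**Figure D1:**
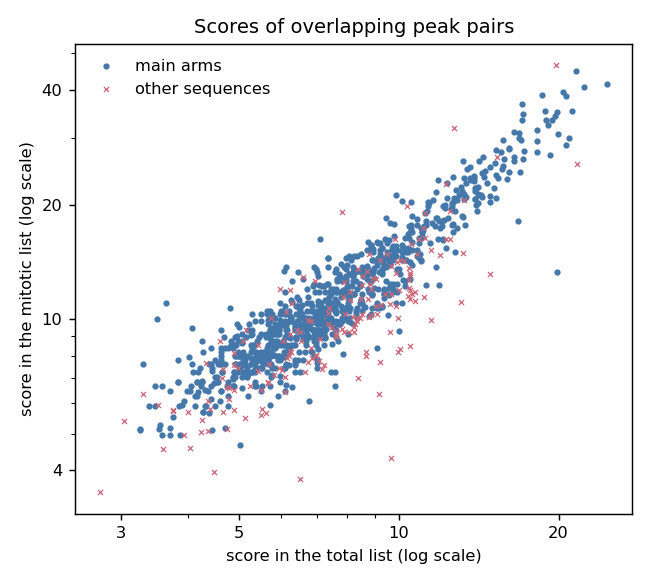
Score of each of the 1092 overlapping peak pairs in the total list (horizontal, log scale) and the mitotic list (vertical, log scale), with circles for the main arms and crosses for other sequences. Sites with a higher total score had a higher mitotic score, with a Spearman rho of 0.89 across pairs.

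The borders of the paired peaks were closely related. In 1090 of 1092 pairs (99.8%, 99.3 to 99.98%) the mitotic peak lay on or within both borders of the total peak. It was narrower in 1066 pairs, equally wide in 26 and wider in 0. Starts were identical to the base pair in 154 pairs (14.1%, 12.1 to 16.3%) and ends in 147 pairs (13.5%, 11.5 to 15.6%). For comparison, each start offset from 1 to 10 bp was seen in a mean of 4.9 pairs. One site with both borders identical was the strong peak on 3R at 3635506 to 3636658, with scores of 21.58 in the total and 44.94 in the mitotic list.

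**Figure D2:**
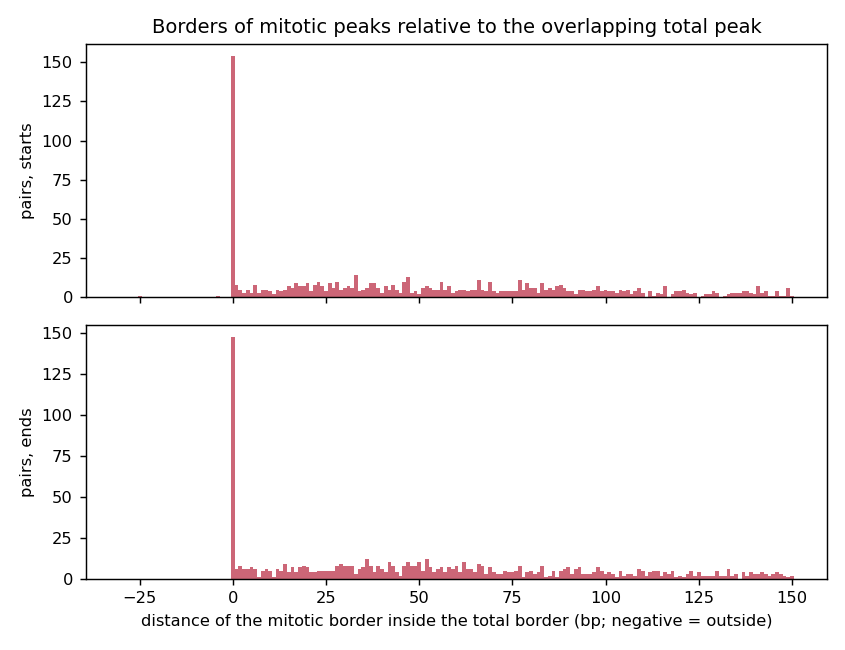
Number of overlapping peak pairs (vertical) by the distance in bp of the mitotic border inside the total border (horizontal, negative values outside), for starts (upper) and ends (lower). The bars at 0 hold 154 starts and 147 ends, 2 starts and 0 ends lie outside, and offsets above 150 bp (208 starts, 226 ends) are not drawn.

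The second question was which total sites lacked a mitotic peak. These were the weaker sites of the total list. The 1087 shared total peaks had a median score of 7.28 and the 850 total-only peaks one of 4.39, a difference of 2.89 (two-sided permutation test over peaks, p = 1e-05, the smallest that the resamples can give). Among the weakest 20% of total peaks 46 of 388 were shared (11.9%, 8.81 to 15.5%). Among the middle 20% 198 of 388 were shared (51.0%, 45.9 to 56.1%). Among the strongest 20% all 387 were shared, and 0 of 387 lacked a mitotic peak, which allows a share of up to 0.775% for counting error only. It is not stated that the lists were called on separate reads. An alternative added after seeing the data took scores as read heights counted in steps. Only 66.1% of mitotic scores lay on such steps, and the assumption is treated in the closing section. With mitotic heights subtracted from the total heights of shared peaks on that assumption, 15 of the 387 then strongest lacked a mitotic peak (3.88%, 2.19 to 6.31%). The strongest total-only peaks lay on 3R at 17313174 to 17314179 (score 8.27), on 3R at 18312360 to 18313439 (score 8.06) and on 2R at 12011886 to 12012963 (score 7.89). A score above 8.27 was reached by 396 total peaks, and each of them was shared.

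**Figure D3:**
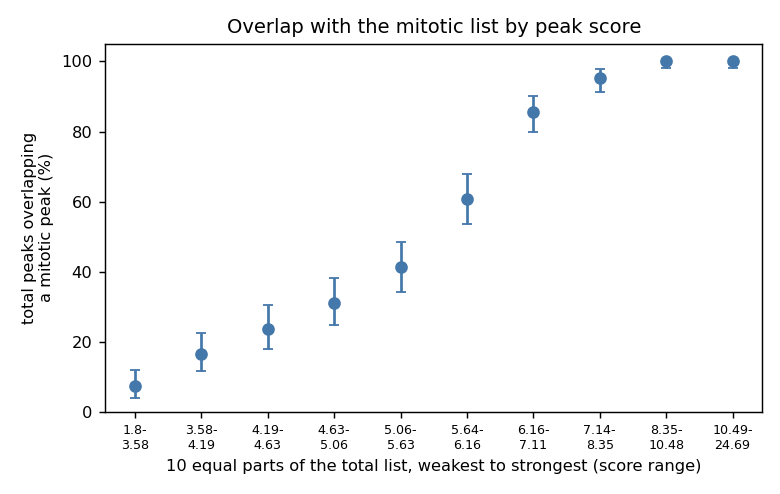
Percentage of total peaks that overlapped a mitotic peak (vertical) in 10 equal parts of the total list ordered by score (horizontal, with the score range of each part). Points are shares and bars exact 95% intervals for counting error; the share rose from 7.22% in the weakest part to 100% in the 2 strongest parts.

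Peaks found only in the mitotic list were few. The 21 mitotic-only peaks had a median score of 8.19, against 10.28 for shared mitotic peaks. This difference of 2.09 did not pass the threshold (two-sided permutation test over peaks, p = 0.053). They were narrower, with a median of 699 bp against 916 bp for shared mitotic peaks (two-sided permutation test of widths, p = 2e-05). Of the 21, 9 were in Uextra and 12 on the main arms. Uextra held 156 shared total peaks and the main arms 916, so Uextra was over-represented among mitotic-only peaks (odds ratio 4.40, Fisher's exact test, two-sided, p = 0.0019, chosen after seeing the data). The test counts peaks as independent, but some in Uextra lie close together, as at 28341745 to 28342217 and 28342332 to 28343200. The 3 strongest were all in Uextra, at 27989974 to 27990929 (score 11.42), 28586986 to 28587861 (score 9.88) and 28341745 to 28342217 (score 9.52). The nearest total peak was a median of 13.2 kb away from a mitotic-only peak. This distance was 2807 to 199964 bp on the main arms and 990 to 13783 bp in Uextra, where positions of unplaced sequence need not reflect genomic distance.

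The third question was where in the genome the sites lay and whether the conditions differed in this. The main arms held 82.5% of total peaks and 83.5% of mitotic peaks, and Uextra held 15.6% and 15.2%. The small chromosome 4 had 8 total peaks, of which 6 were shared. The sequences named Het and U, which collect heterochromatic and unplaced sequence, had 28 total peaks and 9 mitotic peaks. On the X 211 of 343 total peaks were shared (61.5%, 56.1 to 66.7%), and on chromosomes 2 and 3 705 of 1255 (56.2%, 53.4 to 58.9%). This difference did not pass the threshold (odds ratio 1.25, Fisher's exact test, two-sided, p = 0.085). It did when the X was set against all other sequences (odds ratio 1.31, Fisher's exact test, p = 0.027). These include the sequences outside the main arms, where 171 of 339 total peaks were shared (50.4%). Of the 5.34 percentage points between the X and chromosomes 2 and 3, 5.08 were expected from scores, as treated in the closing section. Of the 12 mitotic-only peaks on the main arms, 1 was on the X, against 132 of 682 total-only peaks (odds ratio 0.379, Fisher's exact test, p = 0.48).

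Peaks were sparser on 2L than on 2R, 3R and X in both lists, and the comparison with 3L did not pass in either. The lists do not count as independent observations of this, since 1092 of 1113 mitotic peaks overlapped a total peak. 2L had 9.64 ± 4.63 total peaks per Mb (mean and SD over 22 bins), and 2R had 16.2 ± 6.66 (21 bins). X had 15.5 ± 6.60 (22 bins), 3R had 14.1 ± 5.13 (27 bins) and 3L had 12.5 ± 4.27 (24 bins). In permutation tests over bins, with adjustment over 20 tests, 2L was lower than 2R (adjusted p = 0.0065), X (0.0087) and 3R (0.0088). Against 3L the adjusted p was 0.077. In the mitotic list 2L had 5.50 ± 3.04 peaks per Mb. It was lower than 2R with 9.14 ± 4.02 (permutation test over bins, adjusted p = 0.0087) and X with 9.64 ± 4.02 (adjusted p = 0.0065). It was also lower than 3R with 8.56 ± 3.82 (permutation test, adjusted p = 0.011), and against 3L with 6.63 ± 2.62 the adjusted p was 0.31. 3L was also lower than 2R and X in the mitotic list (permutation tests, adjusted p = 0.04 and 0.011), whereas in the total list these tests gave 0.06 and 0.12. In the stronger 50% of the mitotic list 2L had 2.82 and 2R 3.95 peaks per Mb, which no longer passed (permutation test, unadjusted p = 0.11). In the stronger 50% of the total list the values were 5.05 and 7.29 (permutation test, unadjusted p = 0.018). The densest bin of the total list was on X at 16000001 to 17000000, with 29 total and 19 mitotic peaks. It was followed by 28 total peaks each on 2R at 9000001 to 10000000, on 3R at 5000001 to 6000000 and on X at 15000001 to 16000000.

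**Figure D4:**
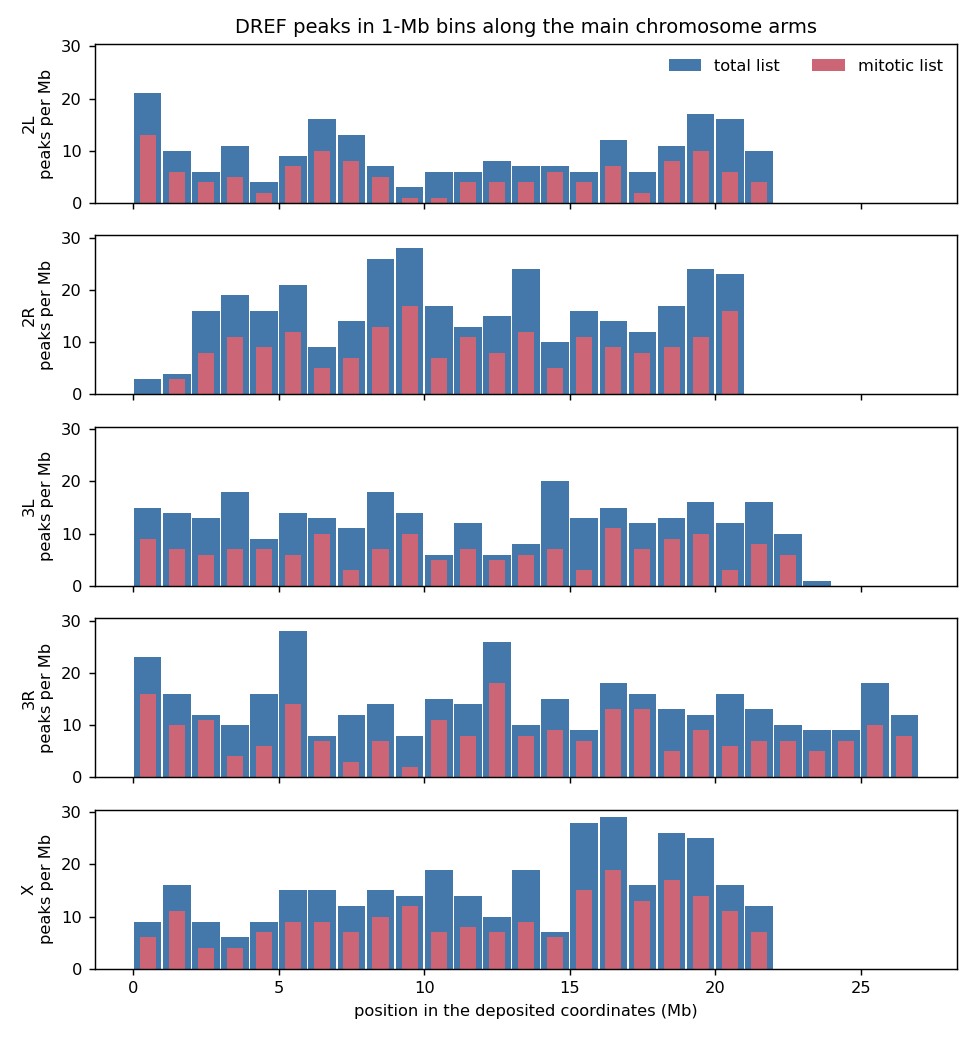
Number of DREF peaks in each 1-Mb bin (vertical) along the main chromosome arms (horizontal, position in Mb in the deposited coordinates), with wide bars for the total list and narrow bars for the mitotic list. 2L had a mean of 9.64 total peaks per Mb against 16.2 on 2R, and the mitotic counts lay below the total counts in each bin drawn.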

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

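Of 39 alternative values, 34 kept their direction and their side of the threshold or stayed within the limits set for counts and widths. The share of mitotic peaks that overlapped a total peak was 82.7% when the total list was reduced to its 1113 strongest peaks and otherwise 97.0 to 99.1%. The share of total peaks that overlapped a mitotic peak was 82.3% with that reduced list and otherwise 55.8 to 57.3%. Since nearly all mitotic peaks lay within total peaks, this share largely follows the ratio of the list lengths. Its constancy is therefore not separate support, and halving both lists hides its relation to strength. Against the whole mitotic list it was 11.9% in the weakest and 100% in the strongest 20% of total peaks. The difference in size between shared and mitotic-only peaks of the mitotic list passed the threshold with width in place of score (216.5 bp). The odds ratio of the X for shared against total-only peaks passed when the X was set against all other sequences (1.31). These include the sequences outside the main arms, where 50.4% of total peaks were shared. The odds ratio of the X for mitotic-only against total-only peaks turned from 0.379 to 1.22 in the stronger 50% of each list, where 4 mitotic-only peaks were left on the main arms and neither value passed. The difference in density between 2L and 2R in the mitotic list was −1.13 peaks per Mb in its stronger 50% and no longer passed, with fewer peaks counted. If scores are taken as read heights counted in steps, mitotic heights can be subtracted from total heights. The share of the strongest 20% of total peaks without a mitotic peak then moved from 0 to 3.88%. The last 2 alternatives, the 2-Mb bins, the omission of the outer bins and the local shifts were chosen after seeing the data. No paired analysis was possible because each condition has 1 list without values per library, and for the same reason no library could be left out. The alternatives for promoters, the motif and the gene lists were not run, because they need a genome and annotation of Release 5. Depth is unknown, so whether a site missing from the mitotic list was unbound or below its detection limit cannot be read from the lists. The same holds for the mitotic-only peaks that are missing from the total list.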

Other observations

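In this part the test of the strong peaks on 2L was set before its result was seen, and all other tests were chosen after seeing the data. Uextra, the collection of unplaced sequence, carried 303 total and 169 mitotic peaks, and the widest peaks of both lists. The widest total peak was there at 28998856 to 29003847 (4992 bp, score 4.37), and the widest mitotic peak at 28815177 to 28819029 (3853 bp, score 6.81). On the main arms the median gap between neighbouring peaks was 39.5 kb in the total list and 77.3 kb in the mitotic list. Gaps under 2 kb numbered 75 in the total list, against a median of 65 in 1000 uniform placements (one-sided permutation p = 0.11), and 24 against 21 in the mitotic list (p = 0.33). The steps of the scores were found by search. Of the mitotic scores 66.1% were whole multiples of 0.1904 (tolerance 0.0055, 5.78% by chance), and of the total scores 81.1% were multiples of 0.0289 (38.0% by chance). The excess over chance was 60.4 points in the mitotic and 43.0 points in the total list, and a search in 20 lists with jittered scores reached at most 19.8 and 18.3 points. On the main arms 74.1% of mitotic and 86.5% of total scores lay on the steps, and in Uextra 24.9% and 54.5%. The Uextra shares were lower than those of the arms and above the shares by chance. The limits from jittered scores are for whole lists and do not measure Uextra alone.

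The mitotic peaks lay on or inside the total peaks, with starts identical in 14.1% of pairs (12.1 to 16.3%). Greater depth of the total list alone is argued against, since identical starts were 31.4 times as frequent as the mean offset of 1 to 10 bp. Limits of unplaced sequence are argued against by 13.1% identical starts on the main arms. Whether borders on the arms meet repeated sequence was not examined. A candidate explanation is that the total list was called on reads that include those of the mitotic libraries. If scores are read heights over a background, mitotic reads would be 15.2% of background reads (from the step ratio of 6.59). They would be a median of 22.4% of the height at paired peaks. The rule used here asked for few mitotic borders outside, which 1090 of 1092 nested pairs met. It also asked the interval of identical starts to hold both shares, and it holds only the former. An interval this narrow could not hold both, so this comparison could not decide for common reads. Which share applies at peak borders is not known, and this candidate explanation stays open. If it holds, the overlap of 98.1%, its comparison with shifted peaks, the correlation of scores and the relation of total score to sharing would be partly built in; no biological explanation was tested.

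Total peaks without a mitotic peak were the weak ones. In the lists, 0% of the strongest 20% lacked a mitotic peak, against 43.9% of all total peaks. If the lists were called on separate reads, this argues against a loss of sites in mitotic cells irrespective of their strength. If they share reads, the relation is partly built in and these values cannot decide. When mitotic heights in steps were subtracted from the total heights of shared peaks, to allow for common reads, the share of the strongest 20% was 3.88% (2.19 to 6.31%). This takes all scores as read heights, although only 66.1% of mitotic and 81.1% of total scores lay on the steps. In Uextra 24.9% of mitotic scores did. Total-only peaks keep their heights, so the subtraction can only raise the share without a mitotic peak here and lower it among the weakest 20%. Among the weakest 20% of total peaks 88.1% lacked one (63.4% after that subtraction), which is consistent with shallower mitotic libraries. A loss of binding at weaker sites in mitotic cells cannot be told apart from this, because depth was not measured and the step ratio of 6.59, if it reflects depth, leaves room for either.

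At equal score, judged by 10000 permutations within 10 equal parts of the total list by score and adjusted over 3 comparisons, Uextra peaks were shared less often than those of the main arms. The excess was −6.88 percentage points (permutation test, adjusted p = 0.0048). With fewer scores on the steps and a lower ratio of mitotic to total score in Uextra, an equal total score may not mean equal strength there. The shared percentage on the X was 5.34 percentage points above that on chromosomes 2 and 3, and 5.08 points were expected from scores. The excess was 0.261 percentage points (permutation test, adjusted p = 0.93), which leaves a difference at equal score open. Neighbouring total peaks on the main arms had the same status in 53.5% of 1593 neighbour pairs, against 51.4% expected from scores (one-sided permutation test, adjusted p = 0.033) and 51.1% when permuted within each arm (p = 0.012). A regional component of overlap may therefore exist, but its size is small and regional coverage was not measured.

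The low density of 2L may reflect lower read coverage or copy number of that arm in these cells. If scores fall with coverage, 2L should then hold a smaller share of the strongest peaks than of the rest. If lower coverage instead kept weak peaks out of the list, the share could be larger, so this test cannot decide. Of the strongest 20% of total peaks, counted on the main arms, it held 11.5% (8.19 to 15.6%), and of the other peaks 13.9% (Fisher's exact test, two-sided, p = 0.31). The median total score was 5.81 on 2L and 5.58 on the other main arms, so listed peaks were not weaker on 2L by this measure. A loss of weak peaks from the list could also leave such a median. Neither value decides, and the explanation stays open.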
